A study of Saccharomyces cerevisiae with 32 samples.

How the data were processed

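Saccharomyces cerevisiae was grown at 25 °C in rich medium (YPD) to an OD600 near 0.8 and then either brought to 37 °C for 15 min with an equal volume of heated medium or mock treated at 25 °C, per the labels. For chromatin immunoprecipitation (ChIP) the cells were then fixed with 1% formaldehyde for 2 h, per the labels. The immunoprecipitated and amplified DNA of heat shocked and mock treated cells was hybridised together on 2-colour arrays of intergenic regions. The 28 ChIP arrays fell into 7 groups of 4, namely HA-tagged TBP, TAF1, Spt3, Mot1 and Bdf1, a strain labelled Null, and input DNA of the TAF1 strain against input DNA of the Spt3 strain. A further 4 arrays of gene probes carried cDNA of the strain labelled Null (BY4741), 2 with heat shocked against mock treated cells and 2 with mock treated cells in both channels.

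Images were read with a GenePix 4000A scanner and GenePix Pro 4.0, per the labels. The background correction, the normalization and the filter on weak spots are not given in the sources used here. The deposited values were log2 ratios of the 2 channels of each array. The log2 scale was taken from the values, which lay on both sides of 0 and in a small share sat exactly at log2 ratios of small whole numbers. The values were not centred, and were taken as not turned by condition. The medians of replicates A to D were 0.21, 0.17, 1.52 and 0.78 for TBP, 0.60, 1.00, 0.20 and 0.36 for TAF1, -0.20, 0.00025, -1.76 and 1.71 for Mot1, 0.48, 0.63, 0.11 and 0.71 for Bdf1, -0.70, 1.77, -0.27 and 0.88 for Null, and 0.33, 1.03, 0.63 and 0.62 for input DNA. For Spt3, replicates B to E, they were -0.74, -0.05, 1.47 and 0.10. On the RNA arrays A and B they were -0.11 and -0.18 for heat against mock, and -0.06 and -0.16 for mock against mock. Each ChIP array held 6644 to 6953 values, and each RNA array held 6865 to 6944.

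Which channel was the numerator is not stated. The 2 heat RNA arrays, of opposite channel order, correlated at r = -0.682 as deposited, so the RNA table had not been turned. The ChIP arrays were less clear. Their pairs of opposite order were at -0.28 to 0.031 for TBP, -0.375 to 0.04 for Mot1 and -0.138 to 0.157 for Bdf1. For TAF1 (0.008 to 0.266), Spt3 (0.034 to 0.217), Null (0.14 to 0.409) and input DNA (0.295 to 0.445) all were above 0. After turning, the TAF1 and Spt3 pairs correlated above 0 only with a fitted channel effect taken off (0.111 to 0.341 and 0.127 to 0.23). That the ChIP values had not been turned was thus an assumption. The RNA values were read as channel 2 over channel 1, because heat shock chaperones then rose. That basis was written before the data were examined, and it makes the chaperone list no independent evidence of direction. The ChIP values were read as channel 1 over channel 2, because the TBP effects at chaperone promoters then ran with the RNA changes. That choice was made after the values were seen. Both directions are therefore likely ones, not stated ones. Under the other reading every ChIP sign and every difference between groups reverses, and higher and lower counts swap, while total counts and sizes stay as they are.

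Each array was turned to heat shocked over mock treated and centred on its median. A linear model was fitted to all 28 ChIP arrays with limma 3.58.1 in R 4.3.3, with 1 heat coefficient per group and 1 channel effect per region shared by all arrays. The input arrays entered as TAF1 strain over Spt3 strain. Regions with a value on at least 3 arrays of every group were tested, which left 6401 of 7047. Two-sided moderated tests against 0 were adjusted by the Benjamini-Hochberg method and called under 0.05. Differences between groups (each factor minus Null, and Spt3 minus TAF1) were contrasts of the same fit. The 4 RNA arrays were fitted in the same way with a heat and a channel coefficient, for 6741 of 7056 probes. The model, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

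Probes were paired with genes by the platform annotation, which gave 1 gene per probe, and by a RefSeq table of 6477 genes (assembly R64) used for names and neighbours. Coordinates were not used here. The side of the named gene on which a region lies was not stated. Among 1335 tandem regions named by a Crick-strand gene followed by another, the TBP effect followed the RNA change of the named gene (Spearman rho 0.42) and not that of the right neighbour (rho -0.005). Among 1354 tandem Watson-strand regions it followed the right neighbour (rho 0.465) and not the named gene (rho -0.022). Regions were therefore placed to the right of the named gene, a choice made after the values were seen, so the relation between TBP and RNA below is not fully independent of it. Of the tested regions, 2689 bordered 1 promoter, 1444 bordered 2 promoters, 1367 lay between convergent genes, 26 could not be placed and 875 had no gene name. A region between convergent genes is called by its left gene and the word downstream.

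The 18 gene lists were heat shock chaperones, general stress response, trehalose and glycogen metabolism, cytosolic ribosomal proteins, ribosome biogenesis, glycolysis and fermentation, translation factors, proteasome, amino acid biosynthesis, respiration and tricarboxylic acid cycle, core histones, ergosterol synthesis, cell wall stress, oxidative stress defence, mitochondrial ribosomal proteins, MATa-specific genes, MATalpha-specific genes and auxotrophy marker loci. Lists with at least 10 members on the arrays were tested with camera (cameraPR in limma) at a preset correlation of 0.01, adjusted over the lists of a comparison. The camera test was repeated with a correlation estimated from the residuals. The rotation test fry was also run, which asks whether the members move on balance one way. The ribosomal protein list was taken by a pattern of symbols that also takes in RPP1, which encodes a subunit of RNase P and not a ribosomal protein.

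Named genes followed 1 rule. For each factor and for RNA these were the 8 largest rises and the 8 largest falls among calls with the same sign on every array of the group, and from each list the 3 called members with the largest effect, or the member with the largest effect where none was called. For RNA and TBP the genes HSP104, SSA4, HSP26, HSP82, SSA1, CTT1, RPL3, RPS3 and ACT1 were added whatever their values. The rule read turned values before the channel effect was taken off.

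Values with 100 regions changed by known amounts were simulated for each comparison of the 6401 regions. At a log2 change of 0.8, calls were made for 83% of changed regions for TBP, 88% for TAF1, 84% for Spt3, 90% for Mot1, 88% for Bdf1 and 87% for Null. At a log2 change of 0.4 these shares were 35%, 38%, 39%, 49%, 44% and 41%. For the difference from Null the shares at 0.8 were 63% for TBP, 68% for TAF1, 63% for Spt3, 67% for Mot1 and 72% for Bdf1, and those at 0.4 were 17%, 18%, 13%, 12% and 12%. For input DNA they were 89% and 40%. For the contrast of Spt3 with TAF1 the shares were 70% at 0.8 and 21% at 0.4. False calls were 4 to 10 per comparison with a factor or Null. The simulation gave all arrays the same spread at a region. Real arrays differed, with median absolute deviations of 0.0920 for input A and 0.497 for Null A. The simulated shares and false calls therefore need not hold for them. Among the 6741 RNA probes, 88% of changes of 1 and 100% of changes of 2 were called, with 25 false calls among 214. On simulated TBP data without change, camera gave 0 of 80 random sets an unadjusted p under 0.05. The simulated regions were independent of each other, so this cannot show whether the preset correlation is high enough for real lists. The number of arrays limits the precision. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between arrays, which may be technical.

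Alternatives were values without centring, no channel effect, other filters on missing values, a fit of each group alone, array weights, arrays scaled to equal spread, pairs of arrays averaged, a block for the replicate letter, a robust prior and each array left out in turn. Lists were also tested with regions of 1 promoter only. Alternatives tested different numbers of regions, so their calls were also given as shares of what was tested, a form chosen while writing, while the comparison with the first fit used counts. Chosen after the data were seen were the alternatives without both noisier Null arrays, with a separate channel effect for input DNA, the arrays left out of list and similarity results, the estimated correlation for sets of RNA-changed genes, the alternatives for promoter classes and their split by direction, the differences between all 10 pairs of factors, and the largest list median under each split. Overlap with Null-corrected effects was set against 20 simulations of unchanged groups that share the Null arrays. Calls under other splits of the 8 arrays of 2 groups were counted for all 35 splits.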

Results

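The data were 28 ChIP arrays of intergenic regions and 4 RNA arrays from budding yeast after 15 min at 37 °C or a mock treatment at 25 °C. Immunoprecipitated factors were TBP (the TATA-binding protein), TAF1 (a subunit of TFIID), Spt3 (a subunit of SAGA known to contact TBP), Mot1 and Bdf1. Mot1 is an ATPase that removes TBP from DNA, and Bdf1 is a bromodomain protein that associates with TFIID. Each factor, the strain labelled Null and an input comparison had 4 arrays. The questions were how occupancy by each factor changed during the stress, whether the changes went with RNA, and whether TFIID and SAGA subunits responded differently. All values are log2 of heat shocked over mock treated cells, relative to each array's median, with the standard error.

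Heat shock changed a large part of the transcriptome. Of 6741 probes, 1223 rose and 1276 fell, and 517 of these rises and 716 of these falls were at least 2-fold. The largest rises were of HSP12, a membrane-protective stress protein, at 8.50 ± 0.34 (limma adjusted p = 3.74e-05), HSP26, a small heat shock protein, at 6.76 ± 0.18 (2.39e-05), and SSA4, a heat-inducible Hsp70, at 6.47 ± 0.21 (2.43e-05). FMP45 rose by 6.25 ± 0.16, the glycogen phosphorylase gene GPH1 by 5.43 ± 0.18, and the hexokinase gene HXK1 by 5.12 ± 0.15. The largest falls were of the flavohemoglobin gene YHB1 (-4.38 ± 0.17), the helicase gene DBP2 (-3.87 ± 0.18), RMT2 (-3.85 ± 0.20), the ribosome assembly gene NOP7 (-3.78 ± 0.21) and URA7 (-3.69 ± 0.16), a CTP synthase gene. The actin gene ACT1 was at -0.04 ± 0.16 (adjusted p = 0.868). With heat array A left out 1331 probes were called, and with heat array B left out 1155. With all arrays scaled to equal spread 259 rose and 428 fell, and the heat arrays alone, without a channel effect, gave 1338 calls.

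Stress and chaperone genes rose together. All 36 general stress genes rose, also when adjusted over the list alone, with a median of 3.32 (camera adjusted p = 1.55e-24). They included DDR2 at 4.70 ± 0.24 and the catalase gene CTT1 at 4.06 ± 0.15. Of 33 heat shock chaperone genes 26 rose and 0 fell (27 and 0 adjusted over the list alone), with a median of 1.20 and an adjusted p of 2.98e-12. HSP104, the disaggregase, rose by 3.02 ± 0.22, HSP82, an Hsp90, by 2.13 ± 0.17, and SSA1, an Hsp70, by 1.20 ± 0.22. The direction of the RNA ratio rests on this list, so its rise is not independent evidence. Of 20 genes of trehalose and glycogen metabolism 17 rose and 0 fell (17 and 1 adjusted over the list alone), with PGM2 at 4.78 ± 0.19, TSL1 at 4.56 ± 0.18 and a median of 1.42 (3.21e-09). Of 33 proteasome genes 20 rose and 0 fell (28 and 0 adjusted over the list alone, median 0.64, 1.33e-06), led by RPN2 at 0.94 ± 0.17. Of 45 genes of respiration and the tricarboxylic acid cycle 27 rose and 0 fell (30 and 0 adjusted over the list alone, median 0.70, 3.21e-09), with the citrate synthase gene CIT1 at 2.98 ± 0.18.

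Genes of the translation machinery fell together. Of 135 cytosolic ribosomal protein genes 133 fell and 0 rose (134 and 1 adjusted over the list alone), with a median of -1.92 (camera adjusted p = 1.5e-39). RPL9A fell to -3.14 ± 0.16, RPS3 to -2.90 ± 0.18 and RPL3 to -1.96 ± 0.15. Of 66 ribosome biogenesis genes 65 fell and 0 rose (66 and 0 adjusted over the list alone), with a median of -2.19 (2.77e-31) and DRS1 at -3.37 ± 0.16. Of 28 translation factor genes 24 fell and 0 rose (25 and 2 adjusted over the list alone, median -1.26, 2.86e-09), with the elongation factor gene YEF3 at -2.51 ± 0.17. Of 10 histone genes 8 fell and 0 rose (8 and 0 adjusted over the list alone, median -0.89, 0.000536), led by HTA2 at -1.30 ± 0.17. With heat array A left out the ergosterol list also passed at an adjusted p of 0.0308.

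The remaining lists were mixed. Of 59 genes of amino acid biosynthesis 9 rose and 20 fell (10 and 23 adjusted over the list alone, median -0.30, camera adjusted p = 0.0181), and ARO4 was lowest at -2.31 ± 0.17. That call was lost without mock array A (0.0772). Of 24 cell wall stress genes 13 rose and 4 fell (13 and 4 adjusted over the list alone, median 0.62, 0.0193), with SED1 at 2.49 ± 0.19. Of 21 genes of oxidative stress defence 10 rose and 2 fell (11 and 2 adjusted over the list alone, median 0.57, 0.00933), with the peroxiredoxin gene PRX1 at 3.02 ± 0.21. This list was not called with an estimated correlation (adjusted p = 0.0608 with an estimated correlation), whereas the other 12 called lists were. Of 65 mitochondrial ribosomal protein genes 11 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.36, 2.04e-05), among them MRP49 at 1.09 ± 0.16. Of 20 glycolysis and fermentation genes 3 rose and 3 fell, the same counts adjusted over the list alone. Their median was -0.20 and their mean 0.29 (0.678), and the risers were the sugar kinase genes HXK1 and GLK1 (3.60 ± 0.16) and the pyruvate kinase gene PYK2 (2.06 ± 0.15). Of 20 ergosterol genes 1 rose and 5 fell, the same counts adjusted over the list alone (median -0.32, 0.063), with ERG3 at -1.69 ± 0.20. Of 7 MATa-specific genes BAR1 (0.55 ± 0.17) rose and MFA1 (-1.34 ± 0.20) fell (0 and 1 adjusted over the list alone, median -0.26). Of 4 MATalpha-specific genes STE3 (0.56 ± 0.16) rose and SAG1 (-0.61 ± 0.19) fell (1 and 1 adjusted over the list alone, median -0.08). Of 7 auxotrophy marker loci ADE2 (1.00 ± 0.18) rose and 0 fell (1 and 0 adjusted over the list alone, median -0.08, mean 0.07).

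**Figure D1:**
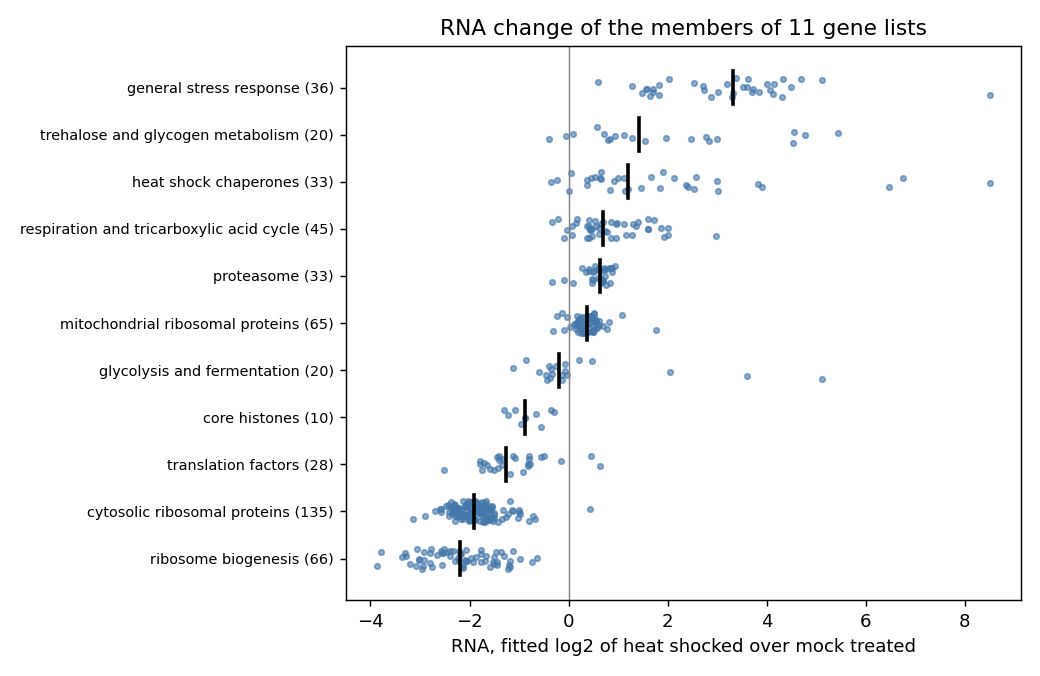
Fitted RNA change (log2, heat shocked over mock treated) of each member of 11 gene lists, with 1 point per gene and a black line at the list's median; numbers in brackets count genes. The general stress list has a median of 3.32 and the ribosome biogenesis list one of -2.19.

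On the ChIP arrays heat shock changed the occupancy of each factor at many regions. The sign of all ChIP values below rests on a likely direction of the ratio. Under the other reading every sign and every difference between groups reverses, and higher and lower counts swap, while total counts and sizes stay. Of 6401 regions 533 were higher and 255 lower for TBP, 782 and 554 for TAF1, 247 and 112 for Spt3, 548 and 267 for Mot1, and 540 and 499 for Bdf1. Changes of at least 2-fold were seen at 11 regions for TBP, 33 for TAF1, 9 for Spt3, 48 for Mot1 and 21 for Bdf1. The median standard error was 0.121 to 0.123. In the Null strain, the background of the immunoprecipitation, 1 region was higher and 1 lower, and 1270 had an unadjusted p under 0.05. The lower one was the promoter of YPL247C (-0.66 ± 0.12, limma adjusted p = 0.0483). Input DNA differed between the TAF1 and Spt3 strains at 1 region, with 36 at an unadjusted p under 0.05. The Null count rested on single arrays, as it was 0 without array A or B (552 and 1156 at an unadjusted p under 0.05), 673 without array C and 352 without array D. With arrays scaled to equal spread 17 were higher and 44 lower for Null, and 30 and 5 for input DNA.

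Tested as a difference from Null, 310 regions were higher and 132 lower for TBP, 475 and 261 for TAF1, 49 and 12 for Spt3, 320 of a total of 443 were higher for Mot1, and 303 higher and 254 lower for Bdf1. Leaving out 1 array moved these counts by more than 1.5 times in several cases. For TBP there were 235 without TBP A, 251 without TBP B and 292 without TBP D. For TAF1 there were 348 without TAF1 A and 405 without TAF1 B. For Spt3 there were 295 without Null C, 187 without Null D, 40 without Spt3 B, 25 without Spt3 C and 39 without Spt3 E. For Mot1 there were 277 without Mot1 C, 276 without Mot1 D and 295 without Null A. For Bdf1 there were 360 without Bdf1 A, 245 without Bdf1 C and 364 without Null B. Without both noisier Null arrays, an alternative chosen after the data were seen, the shares of regions called were 2.28% for TBP (6.91% with them), 4.87% for TAF1 (11.5%), 0.125% for Spt3 (0.953%), 2.22% for Mot1 (6.92%) and 3.19% for Bdf1 (8.70%). Without centring, the median over all regions lay at 0.17 for TBP, -0.15 for TAF1, -0.16 for Spt3, -1.16 for Mot1, -0.20 for Bdf1, -0.91 for Null and -0.17 for input DNA. All changes here are relative to those medians. Without centring no TBP, TAF1 or Bdf1 region was called (278, 206 and 261 at an unadjusted p under 0.05), 1 Spt3 region was lower, and 5710 Mot1 and 5570 Null regions were lower. The differences from Null then gave 3651 higher and 1 lower for TBP, 21 and 0 for TAF1, 10 and 0 for Spt3, and no call for Mot1 or Bdf1 (98 and 1578 at an unadjusted p under 0.05). With array weights the calls against 0 were 2847 for TBP, 1150 for Spt3 and 1638 for Bdf1. With pairs of arrays averaged and no channel effect they were 337 for TBP, 661 for TAF1, 78 for Spt3, 461 for Mot1 and 583 for Bdf1.

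**Figure D2:**
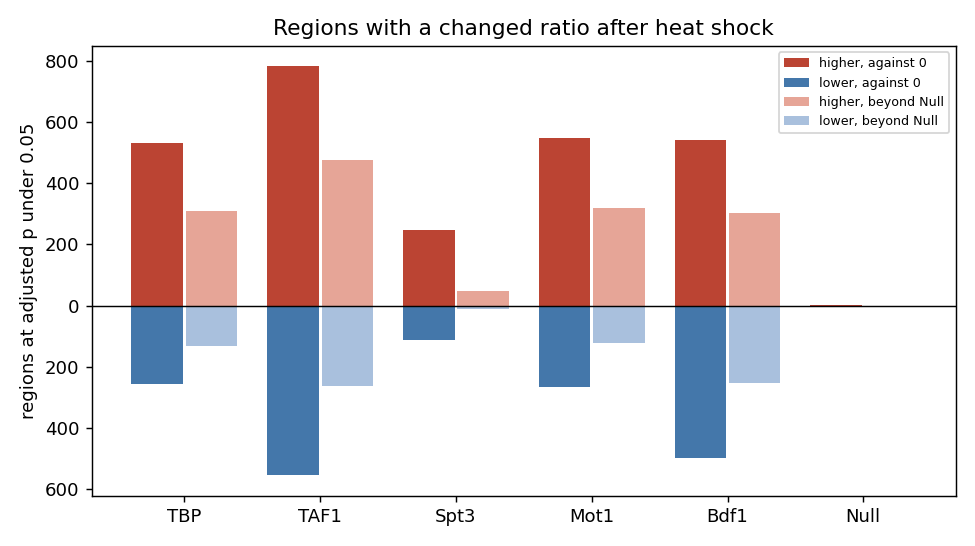
Number of regions called higher (upward bars) and lower (downward bars) after heat shock for each factor and Null, against 0 (dark) and as a difference from Null (light). TAF1 has the most calls against 0, 782 higher and 554 lower, and Null has 1 of each.

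TBP rose at promoters of chaperone, stress, proteasome and respiratory genes and fell at promoters of ribosome biogenesis genes. Of 33 chaperone regions 15 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 4.26e-10). The direction of the ChIP ratio was chosen by TBP at these promoters, so the sign of this change is not independent evidence. SSE2, an Hsp110, rose by 1.05 ± 0.19 (limma adjusted p = 0.000824), HSP104 by 0.98 ± 0.16, the region shared by HSP82 and YAR1 by 0.81 ± 0.12, SSA4 by 0.78 ± 0.16 and HSP26 by 0.25 ± 0.07. UBI4, in the list but encoding polyubiquitin, rose by 1.05 ± 0.15. Of 35 general stress regions 19 rose and 0 fell (22 and 1 adjusted over the list alone, median 0.46, 1.01e-10), with HOR7 at 0.96 ± 0.17 and the aldehyde dehydrogenase gene ALD3 at 0.80 ± 0.14. CTT1, whose RNA rose 4.06, lies beside PDC6 and had values of 0.05 ± 0.17 (adjusted p = 0.9) and 0.49 ± 0.21 (0.127) in 2 regions. Of 31 proteasome regions 19 rose and 0 fell (21 and 0 adjusted over the list alone, median 0.38, 3.29e-13), with PRE4 at 0.73 ± 0.11. Of 45 respiratory regions 15 rose and 0 fell (21 and 0 adjusted over the list alone, median 0.24, 7.76e-10), with ACO1, the aconitase gene, at 0.90 ± 0.29. Of 58 ribosome biogenesis regions 34 fell and 0 rose (45 and 0 adjusted over the list alone, median -0.45, 5.47e-24). The lowest were NOG2 (-1.33 ± 0.21), the region shared by GCD10 and NOP2 (-0.99 ± 0.13) and MAK16 (-0.95 ± 0.22). The actin promoter was at -0.10 ± 0.43 (0.919).

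Among other TBP rises, that of YPR1, an aldo-keto reductase gene, was 1.32 ± 0.14 (limma adjusted p = 8.29e-06) and that of FMP45 was 1.06 ± 0.24. The region shared by RAD10 and GIM5 had the largest estimate, 2.56 ± 0.79 (0.0401), from 3 arrays, of which 2 had its sign once the channel effect was taken off. NRP1 fell to -0.96 ± 0.10 (5.78e-06) and AAH1, the adenine deaminase gene, to -0.88 ± 0.13. Ribosomal protein regions differed little for TBP, with 3 higher and 6 lower of 121 (2 and 5 adjusted over the list alone) and a median of -0.11 (camera adjusted p = 0.00148, adjusted p = 0.479 with an estimated correlation). Their median was -0.25 and -0.37 on TBP arrays A and B but 0.16 and 0.05 on C and D, and the call was lost without array A (0.0628), without array B (0.463) and with fry (0.304). RPS27A rose by 0.64 ± 0.10 while its RNA was at -1.02, and RPL9A fell to -0.52 ± 0.13. Cell wall stress regions (6 rose, 0 fell of 25; 11 and 0 adjusted over the list alone, median 0.23, 0.000376), oxidative stress defence (5 and 0 of 18; 8 and 0 adjusted over the list alone, median 0.30, 0.00288) and trehalose and glycogen (6 and 0 of 18; 8 and 0 adjusted over the list alone, median 0.14, 0.00328) also rose, with the map kinase gene SLT2 at 0.64 ± 0.13, the thioredoxin gene TRX2 at 0.72 ± 0.13 and NTH2, a trehalase gene, at 0.71 ± 0.15. Calls were lost with an estimated correlation for glycolysis (5 and 0 of 19; 6 and 0 adjusted over the list alone, median 0.13, 0.0137, adjusted p = 0.057 with an estimated correlation), ergosterol (3 and 0 of 17; 3 and 0 adjusted over the list alone, median 0.08, 0.0207, adjusted p = 0.0623 with an estimated correlation), translation factors (1 and 2 of 28; 1 and 3 adjusted over the list alone, median -0.10, 0.0207, adjusted p = 0.241 with an estimated correlation) and mitochondrial ribosomal proteins (7 and 1 of 58; 7 and 1 adjusted over the list alone, median 0.15, 0.00148, adjusted p = 0.103 with an estimated correlation). The translation factor call was also lost without array B (0.142) and with fry (0.0828), and that of ergosterol without centring (0.0563). Amino acid biosynthesis was not called (7 and 0 of 55; 7 and 0 adjusted over the list alone, median 0.06, 0.119) but passed with fry (0.000895). In all, 407 regions were called without array A, 426 without array B and 447 without array D.

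TAF1 rose at proteasome and respiratory promoters and fell at ribosome biogenesis promoters. Of 58 ribosome biogenesis regions 41 fell and 0 rose (44 and 0 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 4.46e-23). NOG2 fell to -1.28 ± 0.21 (limma adjusted p = 0.000232), the region of GCD10 and NOP2 to -1.07 ± 0.13 and RPF1 to -1.02 ± 0.14. Of 31 proteasome regions 21 rose and 0 fell (23 and 0 adjusted over the list alone, median 0.44, 1.47e-13), with PRE9 at 0.84 ± 0.10 and RPN2 at 0.77 ± 0.12. Of 45 respiratory regions 22 rose and 0 fell (26 and 0 adjusted over the list alone, median 0.35, 6.9e-09), with KGD1, encoding a subunit of alpha-ketoglutarate dehydrogenase, at 0.84 ± 0.09. Oxidative stress defence had 8 rises and 0 falls among 18 regions (9 and 2 adjusted over the list alone, median 0.32, 0.00155), with TRX2 at 1.00 ± 0.13 and the peroxidase gene GPX1 at 0.91 ± 0.12. Of 33 chaperone regions 8 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.20, 0.000175), with SSE2 at 1.24 ± 0.19 and ERO1, a gene of disulfide formation in the endoplasmic reticulum, at 0.92 ± 0.12. Other large rises were those of the ribonuclease gene RNY1 (1.20 ± 0.19), YLR345W (1.14 ± 0.29) and ROY1 (1.08 ± 0.19). SLM5 had the largest estimate, 2.95 ± 1.01 (0.0468), from 3 arrays.

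These 5 lists kept their TAF1 calls with an estimated correlation. Those lost were general stress (15 rose, 1 fell of 35; 16 and 2 adjusted over the list alone, median 0.15, camera adjusted p = 0.00155, adjusted p = 0.0618 with an estimated correlation), with ALD3 at 1.00 ± 0.14, trehalose and glycogen (4 and 1 of 18; 7 and 1 adjusted over the list alone, median 0.15, 0.0112, adjusted p = 0.0536 with an estimated correlation), translation factors (1 and 5 of 28; 1 and 5 adjusted over the list alone, median -0.11, 0.0191, adjusted p = 0.225 with an estimated correlation), ergosterol (4 and 0 of 17; 6 and 0 adjusted over the list alone, median 0.11, 0.0427, adjusted p = 0.116 with an estimated correlation) and mitochondrial ribosomal proteins (12 and 2 of 58; 13 and 2 adjusted over the list alone, median 0.15, 0.00155, adjusted p = 0.127 with an estimated correlation). With regions of 1 promoter only, general stress (0.149), trehalose and glycogen (0.168) and ergosterol (0.0883) were lost, while cell wall stress (shift of 0.21, 0.0447) and ribosomal proteins (shift of -0.12, 0.0447) passed. Ergosterol was also lost without centring (0.2). Ribosomal proteins (3 and 5 of 121; 2 and 2 adjusted over the list alone, median -0.09, 0.104), cell wall stress (6 and 0 of 25; 6 and 0 adjusted over the list alone, median 0.11, 0.0723), amino acid biosynthesis (10 and 2 of 55; 10 and 2 adjusted over the list alone, median 0.08, 0.135) and glycolysis (2 and 1 of 19; 1 and 1 adjusted over the list alone, median 0.04, 0.498) were not called with all regions and arrays, though fry called cell wall stress (0.00694) and amino acid biosynthesis (0.000363). Leaving out array A ended the ergosterol call (0.104). Without array B the trehalose (0.0779) and translation factor (0.137) calls ended and cell wall stress passed (0.0288). Without array C ribosomal proteins passed (0.00074), and without array D they passed too (0.0152) while ergosterol did not (0.0716). In all, 625 regions were called without array A and 816 without array B. With arrays scaled to equal spread 812 were called, and a fit of the 4 TAF1 arrays alone called 0 (1763 at an unadjusted p under 0.05).

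Spt3 rose at promoters of chaperone, glycolytic and cell wall genes, and none of the ribosome biogenesis regions was called. Of 58 ribosome biogenesis regions 0 rose and 0 fell (0 and 0 adjusted over the list alone), and the median was 0.03 (camera adjusted p = 0.987). The largest effect in that list was 0.70 ± 0.38 at RRP1 (limma adjusted p = 0.31). Of 19 glycolysis and fermentation regions 7 rose and 1 fell (7 and 2 adjusted over the list alone, median 0.26, 0.000187). TDH3, a glyceraldehyde-3-phosphate dehydrogenase gene, rose by 0.90 ± 0.17 and ADH1, an alcohol dehydrogenase gene, by 0.63 ± 0.12. Of 33 chaperone regions 6 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.22, 6.48e-06), with UBI4 at 0.91 ± 0.15 and HSP78, a mitochondrial disaggregase gene, at 0.62 ± 0.10. Of 25 cell wall stress regions 7 rose and 0 fell (10 and 0 adjusted over the list alone, median 0.24, 1.58e-05), with the glucanase gene BGL2 at 0.65 ± 0.16 and the mannoprotein gene CWP1 at 0.55 ± 0.10. Among named regions with the same sign on every array, the largest promoter rises were of ZWF1, the glucose-6-phosphate dehydrogenase gene, at 0.99 ± 0.12 (5.28e-05), and HOR7 at 0.92 ± 0.17. DNF2, picked after its value was seen, had a larger estimate, 1.98 ± 0.46 (0.0163), with 1 array of the other sign. Of the 8 largest falls by the same rule, 5 were at regions between convergent genes, the lowest downstream of BUD21 (-0.88 ± 0.22), and RPL12A fell to -0.59 ± 0.16.

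Also called for Spt3 with an estimated correlation were general stress (6 rose, 1 fell of 35; 12 and 2 adjusted over the list alone, median 0.17, camera adjusted p = 0.000187), amino acid biosynthesis (6 and 0 of 55; 7 and 0 adjusted over the list alone, median 0.12, 0.00107), with the transaminase gene BAT2 at 0.85 ± 0.10, ergosterol (4 and 0 of 17; 4 and 0 adjusted over the list alone, median 0.16, 0.00089), with ERG6 at 0.58 ± 0.09, and oxidative stress defence (2 and 0 of 18; 2 and 0 adjusted over the list alone, median 0.21, 0.00568). Those lost were ribosomal proteins (1 and 7 of 121; 1 and 13 adjusted over the list alone, median -0.16, 6.96e-07, adjusted p = 0.289 with an estimated correlation), proteasome (5 and 0 of 31; 10 and 0 adjusted over the list alone, median 0.20, 5.3e-06, adjusted p = 0.0578 with an estimated correlation), respiration (3 and 0 of 45; 4 and 0 adjusted over the list alone, median 0.14, 0.00132, adjusted p = 0.125 with an estimated correlation) and mitochondrial ribosomal proteins (3 and 0 of 58; 3 and 0 adjusted over the list alone, median 0.07, 0.00537, adjusted p = 0.188 with an estimated correlation). With fry the ribosomal protein call was lost too (0.108), and with regions of 1 promoter only those of amino acid biosynthesis (0.0774) and mitochondrial ribosomal proteins (0.0611). Trehalose and glycogen (0 and 0 of 18; 0 and 0 adjusted over the list alone, median 0.07, 0.0928) and translation factors (2 and 0 of 28; 2 and 0 adjusted over the list alone, median 0.05, 0.0698) were not called. Leaving out array B ended the respiration (0.0745) and mitochondrial ribosomal (0.156) calls. Translation factors passed without array C (0.0338) or D (0.0424), and trehalose and glycogen without array D (0.0173) or with fry (0.0359). In all, 129 regions were called without array B, 131 without array C and, without array E, 119 higher and 37 lower. With arrays scaled to equal spread 620 were called, and a fit of the 4 Spt3 arrays alone called 0 (1063 at an unadjusted p under 0.05).

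Mot1 rose, relative to the array medians, at chaperone, stress, glycolytic, cell wall and histone promoters and fell at ribosome biogenesis promoters. Of 33 chaperone regions 19 rose and 0 fell (20 and 1 adjusted over the list alone, median 0.49, camera adjusted p = 1.5e-12), led by HSP78 at 1.36 ± 0.10 (limma adjusted p = 1.78e-08). Of 35 general stress regions 18 rose and 1 fell (20 and 1 adjusted over the list alone, median 0.36, 1.76e-11), with the glycerol-3-phosphate dehydrogenase gene GPD1 at 1.14 ± 0.13 and HOR7 at 1.08 ± 0.18. Of 25 cell wall stress regions 13 rose and 0 fell (14 and 1 adjusted over the list alone, median 0.47, 8.13e-09), with CWP1 at 0.85 ± 0.10. Of 19 glycolysis and fermentation regions 9 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.31, 1.69e-06). TDH3 rose by 1.52 ± 0.17 while its RNA was at -0.03, the pyruvate decarboxylase gene PDC1 by 1.01 ± 0.15 with RNA at -0.34, and ADH1 by 0.86 ± 0.12 with RNA at -0.07. Of 6 histone regions 5 rose and 0 fell, the same counts adjusted over the list alone, with a median of 0.35, among them the regions shared by HTA2 and HTB2 (0.56 ± 0.13) and by HHF1 and HHT1 (0.48 ± 0.10), whose RNA fell. For the other factors 0 or 1 of these 6 was called in either direction. Of 58 ribosome biogenesis regions 21 fell and 0 rose (29 and 1 adjusted over the list alone, median -0.24, 1.5e-12), with NOG2 at -0.92 ± 0.22 and SOF1 at -0.78 ± 0.14. CCW22, a cell wall protein gene, rose by 1.44 ± 0.13, ZWF1 by 1.39 ± 0.12 and YPR1 by 1.33 ± 0.15.

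Further Mot1 calls were trehalose and glycogen (8 rose, 0 fell of 18; 9 and 0 adjusted over the list alone, median 0.32, camera adjusted p = 1.09e-05), oxidative stress defence (6 and 0 of 18; 9 and 0 adjusted over the list alone, median 0.32, 0.000423), with AHP1, beside YLR108C, at 1.12 ± 0.17, respiration (13 and 0 of 45; 16 and 0 adjusted over the list alone, median 0.18, 5.42e-05), with CIT1 at 1.00 ± 0.18, ergosterol (4 and 0 of 17; 5 and 1 adjusted over the list alone, median 0.24, 0.00507) and amino acid biosynthesis (10 and 3 of 55; 13 and 3 adjusted over the list alone, median 0.10, 0.0141), with BAT2 at 1.09 ± 0.10. All 10 Mot1 list calls held with an estimated correlation. Without centring those of ergosterol (0.167) and amino acid biosynthesis (0.174) were lost, the second also with regions of 1 promoter only (0.116), where translation factors passed (shift of -0.12, 0.0379). Proteasome (3 and 0 of 31; 3 and 0 adjusted over the list alone, median 0.06, 0.0535), ribosomal proteins (2 and 4 of 121; 1 and 1 adjusted over the list alone, median -0.04, 0.0983), translation factors (3 and 4 of 28; 4 and 4 adjusted over the list alone, camera adjusted p = 0.417) and mitochondrial ribosomal proteins (2 and 2 of 58; 2 and 2 adjusted over the list alone, median -0.01, mean 0.06, 0.791) were not called. Without array B proteasome (0.000552) and ribosomal proteins (0.00268) passed, and without array D ribosomal proteins did (0.0242). Without a channel effect proteasome passed as well (0.00885). In all, 472 regions were called without array C and 449 without array D. A fit of the 4 Mot1 arrays alone called 203.

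Bdf1 fell at ribosome biogenesis promoters, rose at proteasome promoters and went both ways at stress promoters. Of 58 ribosome biogenesis regions 33 fell and 0 rose (43 and 0 adjusted over the list alone, median -0.47, camera adjusted p = 1.32e-21), with MAK16 at -1.15 ± 0.22 (limma adjusted p = 0.00127) and the region of GCD10 and NOP2 at -1.14 ± 0.13 (6.37e-06). The region of RPA43 and RPA190, genes of RNA polymerase I subunits, fell to -1.11 ± 0.13. Of 31 proteasome regions 16 rose and 0 fell (20 and 0 adjusted over the list alone, median 0.33, 2.14e-09), with RPT6, beside ALG13, at 0.60 ± 0.11. Of 33 chaperone regions 4 rose and 4 fell (4 and 6 adjusted over the list alone, median 0.01, mean -0.01, 0.848). ERO1 rose by 0.69 ± 0.12 and SSE2 by 0.69 ± 0.19, whereas the small heat shock protein gene HSP42 fell to -0.51 ± 0.10. Of 35 general stress regions 5 rose and 5 fell (8 and 5 adjusted over the list alone, median 0.02, 0.635), with the region of PAI3 and SIP18 at 1.04 ± 0.14 and HOR7 at -0.80 ± 0.18 (0.00372). HOR7, the glycogen synthase gene GSY2 (-0.77 ± 0.14), CWP1 (-0.46 ± 0.10) and HXK1 (-0.52 ± 0.09) thus fell for Bdf1 where TBP rose, at 0.96, 0.57, 0.49 and 0.54. YLR345W had a large rise, 1.41 ± 0.29, and so had YNL092W (1.17 ± 0.23).

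Respiration (6 rose, 0 fell of 45; 6 and 0 adjusted over the list alone, median 0.13, camera adjusted p = 0.0079, adjusted p = 0.297 with an estimated correlation) and mitochondrial ribosomal proteins (7 and 1 of 58; 7 and 1 adjusted over the list alone, median 0.12, 0.0079, adjusted p = 0.297 with an estimated correlation) lost their Bdf1 calls, also with regions of 1 promoter only (0.057 for both). The ribosome biogenesis and proteasome calls held. Not called were oxidative stress defence (5 and 1 of 18; 7 and 1 adjusted over the list alone, median 0.14, 0.0518), translation factors (1 and 4 of 28; 2 and 7 adjusted over the list alone, median -0.14, 0.0682), ergosterol (4 and 0 of 17; 4 and 0 adjusted over the list alone, median 0.05, 0.144), ribosomal proteins (10 and 4 of 121; 9 and 4 adjusted over the list alone, camera adjusted p = 0.539), with RPP1, an RNase P gene, at -0.59 ± 0.09, trehalose and glycogen (3 and 2 of 18; 3 and 3 adjusted over the list alone, median -0.01, mean 0.01, 0.705), glycolysis (0 and 1 of 19; 0 and 1 adjusted over the list alone, median 0.04, mean -0.02, 0.635), amino acid biosynthesis (5 and 3 of 55; 5 and 3 adjusted over the list alone, median 0.01, 0.376) and cell wall stress (0 and 3 of 25; 0 and 3 adjusted over the list alone, median -0.07, 0.539). Without array A ribosomal proteins (0.0164), ergosterol (0.0408) and oxidative stress defence (0.0408) passed, without array B translation factors (0.0362), and without array C oxidative stress defence (0.0142). With fry oxidative stress defence (0.000194), ergosterol (0.0124) and amino acid biosynthesis (0.0215) passed, and without a channel effect oxidative stress defence (0.0326) and translation factors (0.0198). In all, 427 regions were called without array C and 658 without array D. A fit of the 4 Bdf1 arrays alone called 352.

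No list was called in the Null strain, where the lowest camera adjusted p of the 14 tested lists was 0.211. Its medians were -0.08 for chaperones, -0.05 for general stress, 0.03 for proteasome and 0.03 for ribosome biogenesis. Without Null array A, trehalose and glycogen (-0.11, 0.0457) and ribosomal proteins (0.07, 0.0183) passed. In input DNA the ribosome biogenesis list passed with a median of -0.02 (0.038, adjusted p = 0.712 with an estimated correlation).

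**Figure D3:**
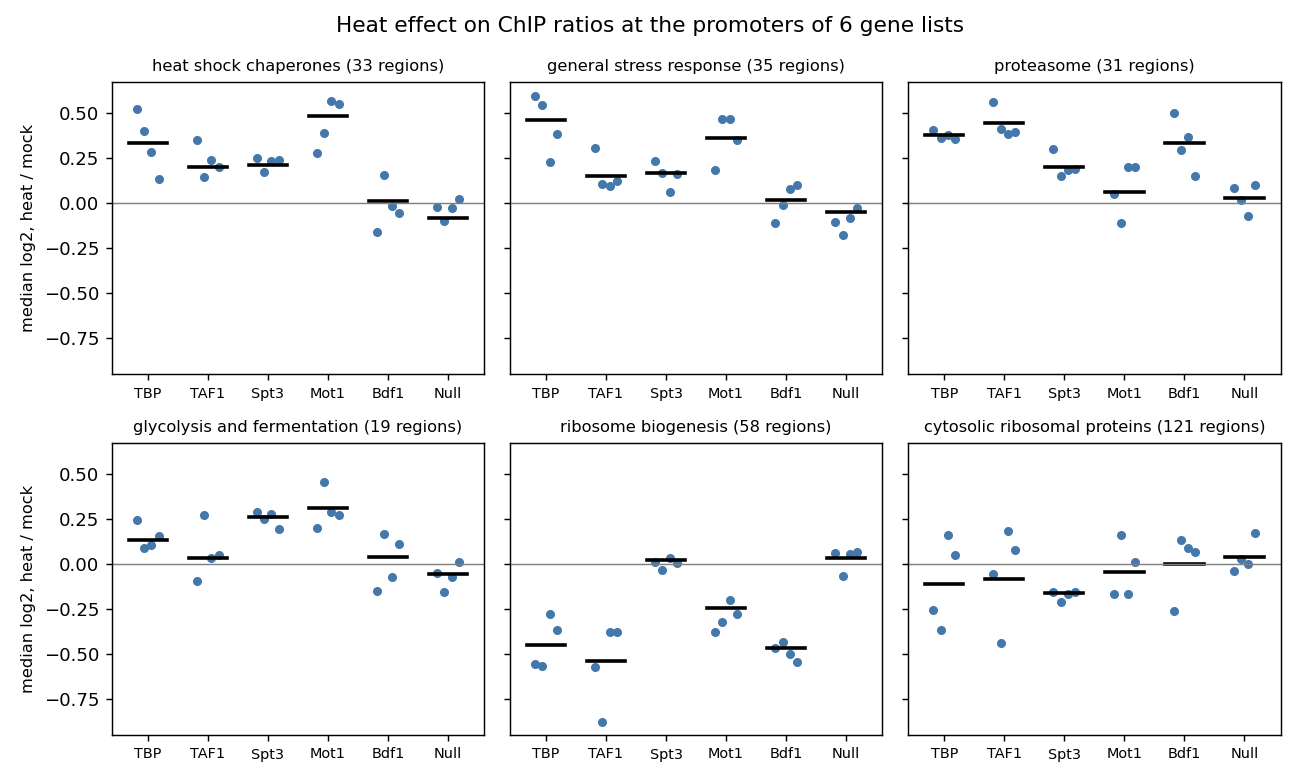
Median heat effect (log2, relative to each array's median) over the regions of 6 gene lists, with 1 point per array (channel effect removed) and a black line at the median of the fitted effects; each panel gives its number of regions. At ribosome biogenesis promoters the fitted medians are -0.45 for TBP, -0.54 for TAF1, -0.24 for Mot1 and -0.47 for Bdf1, but 0.03 for Spt3 and 0.03 for Null.

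TAF1 and Spt3, subunits of TFIID and SAGA, were compared directly. Ribosome biogenesis promoters separated them most, with 22 regions higher and 0 lower for Spt3 minus TAF1 of 58 (37 and 0 adjusted over the list alone) and a median difference of 0.57 (camera adjusted p = 5.52e-25), which held with an estimated correlation (0.000771). At proteasome promoters the difference ran the other way, with 0 higher and 6 lower of 31 (0 and 8 adjusted over the list alone, median -0.27, 2.83e-05, adjusted p = 0.132 with an estimated correlation). Over all regions 255 differences were called, 132 of them positive. The other lists called were respiration (0 and 1 of 45; 0 and 5 adjusted over the list alone, median -0.15, 0.000472, adjusted p = 0.132 with an estimated correlation), translation factors (1 and 0 of 28; 4 and 0 adjusted over the list alone, median 0.22, 0.000249, adjusted p = 0.132 with an estimated correlation), glycolysis (0 and 0 of 19; 0 and 0 adjusted over the list alone, median 0.23, 0.0265, adjusted p = 0.132 with an estimated correlation) and ribosomal proteins (2 and 2 of 121; 2 and 3 adjusted over the list alone, median -0.09, 0.0308, adjusted p = 0.701 with an estimated correlation). The glycolysis call was lost with fry (0.0646) and without Spt3 E (0.0599), TAF1 A (0.0569), TAF1 C (0.0959) or TAF1 D (0.0914). That of ribosomal proteins was lost without Spt3 C (0.11), TAF1 C (0.83) or TAF1 D (0.313), and also with fry (0.539), without a channel effect (0.0558), without centring (0.12) and with regions of 1 promoter only (0.404). Trehalose and glycogen (0.029) and mitochondrial ribosomal proteins (0.0497) passed without Spt3 B, cell wall stress (0.0222) without Spt3 D, and oxidative stress defence (0.0406) with fry. The count of regions was 139 without Spt3 C, 141 without Spt3 E, 106 without TAF1 A and 92 without TAF1 B. It was 94 higher and 58 lower with arrays scaled to equal spread, and 0 without centring (77 at an unadjusted p under 0.05) or in a fit of the 8 arrays alone (1044).

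Read in the likely direction, promoters of induced genes were higher on balance for all 5 factors. The sign of the relation between TBP and RNA was set by the choice of direction and of region side, so it is no finding, and under the other reading all values here reverse. Of 992 regions at promoters of genes whose RNA rose, 290 were higher and 16 lower for TBP (median 0.20), 349 and 29 for TAF1 (0.21), 99 and 8 for Spt3 (0.10), 214 and 16 for Mot1 (0.13) and 221 and 51 for Bdf1 (0.14). With an estimated correlation camera gave adjusted p-values of 8.48e-07, 8.09e-06, 0.00855, 0.000378 and 0.00136. Null had 0 higher and 1 lower of these regions (median -0.03, adjusted p = 0.107), but passed without array A (shift of -0.04 against other regions). At genes induced at least 2-fold Bdf1 had 90 higher and 37 lower of 432 regions (camera adjusted p = 0.000245) and lost its call with an estimated correlation (adjusted p = 0.0734), though as a difference from Null it kept it (0.0445). The other 4 factors kept theirs. Of 986 regions of genes whose RNA fell, 36 were higher and 127 lower for TBP (median -0.09, 5.29e-07, adjusted p = 0.0518 with an estimated correlation) and 53 and 209 for TAF1 (-0.10, 4.74e-07, adjusted p = 0.0517 with an estimated correlation). Mot1 had 68 and 114 (-0.07, 0.000508, adjusted p = 0.181 with an estimated correlation) and Bdf1 48 and 168 (-0.10, 9.33e-06, adjusted p = 0.0822 with an estimated correlation). Spt3 had 34 higher and 11 lower (0.04, 0.17), and passed without array C (shift of 0.05). Null had 0 and 0 (0.03, 0.0365, adjusted p = 0.428 with an estimated correlation), and its call ended without array D (shift of 0.03). At genes that fell at least 2-fold, TBP had 12 higher and 109 lower of 556 regions (-0.15, adjusted p = 0.0226 with an estimated correlation) and TAF1 had a median of -0.17 (adjusted p = 0.0333 with an estimated correlation). Mot1 (camera adjusted p = 2.74e-05, adjusted p = 0.186 with an estimated correlation) and Bdf1 (7.97e-09, adjusted p = 0.0676 with an estimated correlation) lost their calls there. As differences from Null, with an estimated correlation, Bdf1 kept its call (0.0468) and so did TBP and TAF1, also over all 986 regions (0.0461 and 0.0402). Across 4859 genes, which are not independent replicates, the correlation of occupancy change with RNA change was r = 0.444 (rho = 0.427) for TBP, 0.402 (0.414) for TAF1, 0.321 (0.289) for Mot1, 0.275 (0.335) for Bdf1, 0.125 (0.121) for Spt3 and -0.094 (-0.104) for Null.

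**Figure D4:**
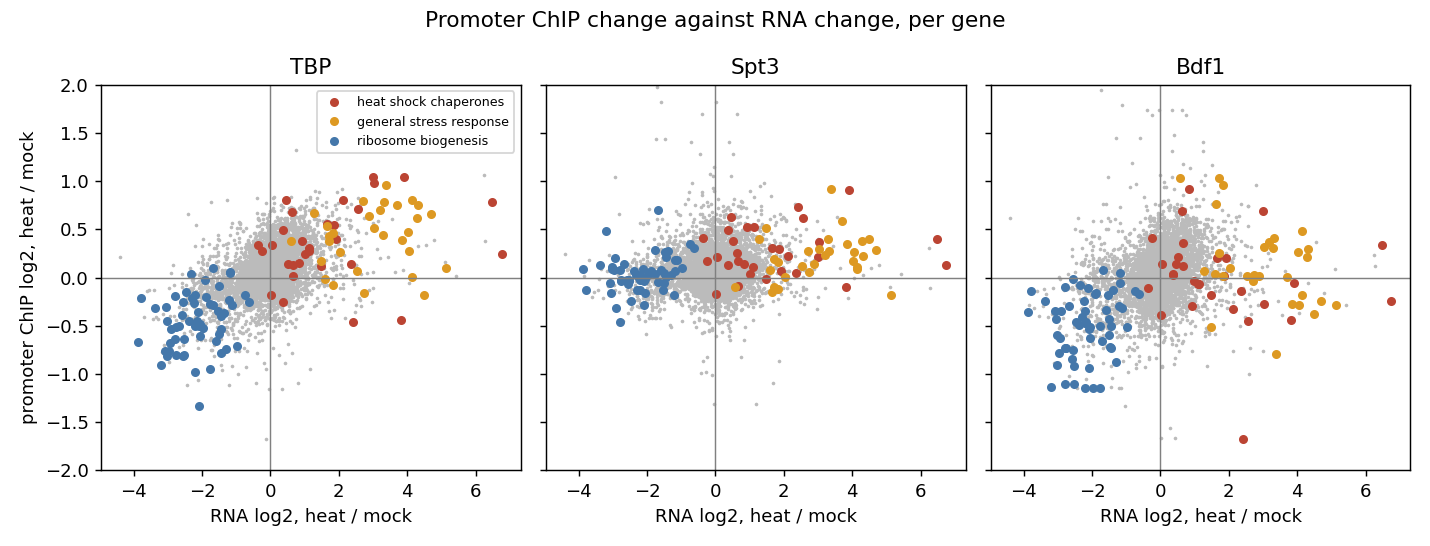
Change in promoter ChIP ratio (vertical, log2) against change in RNA (horizontal, log2) for each gene, for TBP, Spt3 and Bdf1, with chaperone, general stress and ribosome biogenesis genes coloured; 8 genes lie outside the vertical range of at least 1 panel. Ribosome biogenesis genes lie below 0 on balance for TBP (median -0.45) and Bdf1 (-0.47) and around 0 for Spt3 (0.03).

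Higher calls lay at promoters more often than between convergent genes for all 5 factors. For lower calls the shares ran that way for Mot1 and TBP, and passed the test for Mot1. Mot1 was not tested against the other factors in this. For TBP 16.0% of 4133 promoter regions and 4.83% of 1367 convergent regions were called (odds ratio 3.77, Fisher's exact test, two-sided, adjusted p = 9.43e-30). The shares were 24.8% and 12.9% for TAF1 (2.23, 3.06e-21), 15.4% and 5.27% for Mot1 (3.27, 1.03e-24), 18.8% and 11.6% for Bdf1 (1.78, 2.37e-10) and 6.10% and 4.10% for Spt3 (1.52, 0.00688). The Spt3 difference was lost without array D (odds ratio 1.04, Fisher's exact test p = 0.831) and as a difference from Null (2.04, adjusted p = 0.0755). With 1 array left out the odds ratio ranged from 4.08 to 7.69 for TBP and from 2.36 to 5.62 for Mot1. Split by direction after the data were seen, higher calls made up 11.8% of promoter and 0.878% of convergent regions for TBP, 16.7% and 2.12% for TAF1, 5.08% and 0.805% for Spt3, 10.5% and 2.05% for Mot1, and 11.1% and 2.93% for Bdf1, where the largest adjusted p of Fisher's exact test was 3.99e-15. Lower calls were rarer at promoters for TAF1 (8.03% and 10.8%, Fisher's exact test adjusted p = 0.00333) and Spt3 (1.02% and 3.29%, 9.64e-08). They were more frequent there for Mot1 (4.94% and 3.22%, 0.0104) and not called different for TBP (4.26% and 3.95%, 0.697) or Bdf1 (7.74% and 8.63%, 0.333). Regions are not independent of their neighbours, so these p-values describe the regions of these arrays.

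The effects of TBP and TAF1 were most alike, at r = 0.612 (rho = 0.661) across 6401 regions, which are not independent replicates. Both were higher at 396 regions, where independent lists would share 65.1, and called in opposite directions at 1 (77.3 if independent). TAF1 and Bdf1 were at r = 0.491, TBP and Bdf1 at 0.386, Spt3 and Mot1 at 0.394, and TBP and Mot1 at 0.369 (0.242 to 0.408 with 1 array left out). The lowest values were those of Spt3 with Bdf1 (0.111, and 0.0519 to 0.139 with 1 array left out) and of Mot1 with Bdf1 (0.107), which turned to -0.0124 without Mot1 array D. Most Mot1 and most Bdf1 arrays had opposite channel orders, so the value of this pair leans on the shared channel effect. Over regions with a value on every array TBP and Spt3 were at 0.396, against 0.259 over all (0.145 to 0.292 with 1 array left out). Mot1 and Bdf1 were called in opposite directions at 58 regions (65.2 if independent), TAF1 and Bdf1 at 2 (107.7). Each factor's correlation with Null was between -0.048 and 0.089. As differences from Null the 5 factors share the Null arrays, and r rose to 0.812 for TBP with TAF1 and 0.546 for Mot1 with Bdf1, where unchanged groups sharing those arrays gave 0.510 and 0.482. The covariances were 0.1501 and 0.101 against simulated values of 0.0460 and 0.0442, differences of 0.104 and 0.0568. The simulation gave all arrays the same spread at a region. Null A and B had median absolute deviations of 0.497 and 0.377, against 0.158 and 0.139 on Null C and D. The simulated covariance from shared Null arrays may thus be too low, so these differences do not measure a shared response. With the Null arrays split between the factors of a pair r was 0.190 and 0.0014.

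**Figure D5:**
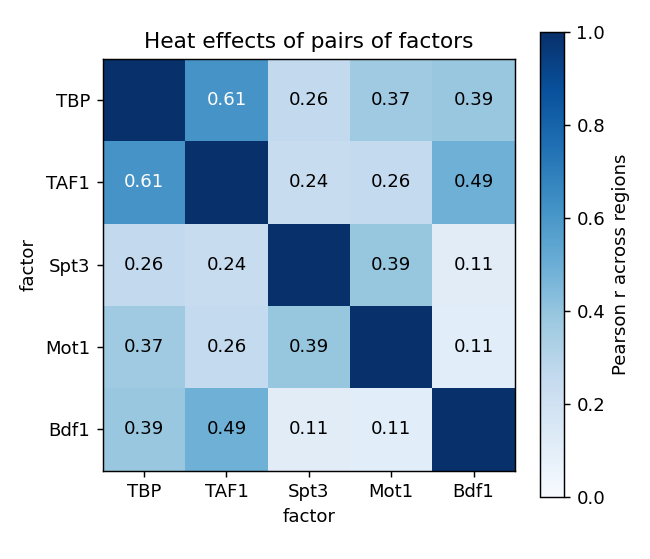
Pearson correlation across 6401 regions between the heat effects of each pair of factors, from 0 (white) to 1 (dark). TBP with TAF1 is highest at 0.61 and Mot1 with Bdf1 among the lowest at 0.11.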

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

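Chosen only after the results were seen were the tests of input DNA at ribosome biogenesis promoters and of other splits over the gene lists, of the Null background at glycolytic promoters and of the direction of TAF1 calls between convergent genes, as well as all differences between pairs of factors other than Spt3 minus TAF1.

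Within groups of 4 arrays, a gap test (Dixon's ratio) was run on 69 groups of values and set apart 1 array in 7 of them, where chance alone would mark about 1 in 20. The median absolute deviation of Spt3 replicate B was 0.451, against 0.194 to 0.218 on the other Spt3 arrays. Null replicate A lacked 403 values, against 233 to 259. The median absolute deviation of input replicate A was 0.0920, against 0.127 to 0.133. On TAF1 replicate A the median over general stress promoters was 0.31, against 0.09 to 0.12 on the others, and over proteasome promoters 0.56, against 0.39 to 0.41. On Spt3 replicate D the median over amino acid biosynthesis promoters was 0.0769, against 0.14 to 0.16. On Mot1 replicate A the median over ergosterol promoters was 0.12, against 0.22 to 0.24. Each of these 4 list medians had the same sign on all arrays of its group.

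Set apart because 2 groups differed by an adjusted test were 442 regions for TBP against Null, 736 for TAF1, 61 for Spt3, 443 for Mot1 and 557 for Bdf1, and 255 for Spt3 against TAF1. Among the 35 splits of the 8 arrays into 4 and 4, the true one ranked 1 in each of these 6 cases. The highest other counts were 41, 68, 8, 74, 3 and 7, so chance in the grouping is unlikely in each case. It is not excluded, as 1 of 35 is the smallest share possible and was not adjusted over the 6 cases. Arrays that may not be separate cultures also limit what the splits can show. With the signs of some of the 4 arrays of a group turned there are only 8 patterns, too few for a share under 0.05. The true pattern gave 788 calls for TBP (highest other 6), 1336 for TAF1 (2), 359 for Spt3 (6), 815 for Mot1 (215) and 1039 for Bdf1 (1), each ranking 1, and 2 for Null (26), ranking 4.

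The first pattern weighed is that Spt3 did not fall at ribosome biogenesis promoters while TAF1 did, with a median of Spt3 minus TAF1 of 0.57 over 58 regions (camera adjusted p = 5.52e-25, and 0.000771 with an estimated correlation). Since the list was picked as the most different of 14, the largest median of any list was taken under each of the 35 splits. The true one ranked 1 (0.566, highest other 0.430), which makes chance in the grouping unlikely without excluding it. A weaker response of the Spt3 arrays at every region could give such a difference. With the TAF1 median of -0.54 scaled by the slope of Spt3 on TAF1 (0.195), a median of 0.12 was left. Its spread of 0.0308 was taken over the Spt3 arrays only, with the TAF1 effects and the slope held fixed. Noise in the TAF1 effects also flattens such a slope, so it does not measure how strongly Spt3 responded. How much of the 0.57 a weaker response could account for is thus left open. The input arrays, with a median of -0.0245 over the list (spread 0.0509), compare strains and not heat with mock, so they decide nothing here. Over this list the median was also 0.50 for Spt3 minus TBP, -0.48 for Bdf1 minus Spt3 and -0.29 for Mot1 minus Spt3. Camera with an estimated correlation gave adjusted p-values of 0.00198, 0.00943 and 0.0217. Spt3 thus stood apart from each other factor here, not from TAF1 alone. A true difference between the SAGA and TFIID subunits at these promoters may remain, though 4 arrays of each and 1 strain per factor cannot separate the factor from its tag. The arrays compare heat with mock, so they do not show whether Spt3 was bound there before heat shock. A lack of Spt3 signal at these promoters would give the same result as unchanged binding.

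Other list medians of Spt3 minus TAF1 passed at the preset correlation only. They were proteasome, -0.27 (2.83e-05), respiration, -0.15 (0.000472), translation factors, 0.22 (0.000249), glycolysis, 0.23 (0.0265), and ribosomal proteins, -0.0946 (0.0308). With an estimated correlation the adjusted p was 0.132 for the first 4 and 0.701 for the last.

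The second pattern is the small TBP change at ribosomal protein promoters, whose RNA fell to a median of -1.92. The median over 121 regions was -0.11 (camera adjusted p = 0.00148, and 0.479 with an estimated correlation). Sharing with a second promoter could dilute the change, and the 57 regions of 1 promoter had a median of -0.14, against -0.50 at the 34 such regions of ribosome biogenesis genes, but the spread of 0.27 between arrays leaves this open. Compressed ratios at heavily occupied promoters could do it as well, and the spread of TBP effects there was 0.528 times that of 4012 other promoter regions, which cannot tell compression from a uniform response. The TBP arrays themselves disagreed, with medians of -0.25 and -0.37 on A and B and 0.16 and 0.05 on C and D.

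The third pattern is the rise of Mot1 at glycolytic promoters, where RNA was unchanged on balance. The median was 0.31 over 19 regions (camera adjusted p = 1.69e-06). An unequal channel order of the Mot1 arrays could cause it, but with both orders weighted equally the shift was 0.35 (0.31 to 0.37 over pairs of arrays). This makes that cause less likely. It cannot exclude it, because array D, the only one of the other order, was part of every pair. Background of the immunoprecipitation could rise at strongly transcribed genes, but the Null median over the list was -0.0538 (spread 0.0692). This argues against such a rise in the Null strain. Background in the Mot1 strain itself was not measured, so it is less likely but not excluded. A rise of Mot1 itself may remain, and it fell short of differing from TBP there (0.22, adjusted p = 0.0793 with an estimated correlation).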

How the results depend on the processing

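Chosen only after the results were seen were the separate channel effect for input DNA, the analysis without both noisier Null arrays, arrays left out of list, set, class and similarity results, the estimated correlation for sets of RNA-changed genes, and the alternatives for promoter classes.

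Calls are given here as shares of the regions or probes tested, since alternatives tested different numbers. With all arrays and the settings used above they were 12.3% for TBP, 20.9% for TAF1, 5.61% for Spt3, 12.7% for Mot1, 16.2% for Bdf1, 0.0312% for Null and 0.0156% for input DNA. Beyond Null they were 6.91% for TBP, 11.5% for TAF1, 0.953% for Spt3, 6.92% for Mot1 and 8.70% for Bdf1, and 3.98% for Spt3 against TAF1 and 37.1% for RNA.

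Centring moved every ChIP count except that of input DNA. Without it the shares were 0% for TBP, 0% for TAF1, 0.0156% for Spt3, 89.2% for Mot1, 0% for Bdf1 and 87.0% for Null. Beyond Null they were 57.1% for TBP, 0.328% for TAF1, 0.156% for Spt3, 0% for Mot1 and 0% for Bdf1, and 0% for Spt3 against TAF1. By construction the shift of an array's median then enters every region and its spread between arrays enters every error.

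With array weights the shares were 44.5% for TBP, 18.0% for Spt3, 25.6% for Bdf1, 0.250% for Null and 0.344% for input DNA. Beyond Null they were 21.8% for TBP, 5.12% for Spt3 and 13.1% for Bdf1, and 11.8% for Spt3 against TAF1. With arrays scaled to equal spread they were 12.7% for TAF1, 9.69% for Spt3, 0.953% for Null and 0.547% for input DNA. Beyond Null they were then 6.61% for TAF1 and 2.64% for Spt3, with 2.37% for Spt3 against TAF1 and 10.2% for RNA. The cause of these moves was not tested.

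With arrays of adjacent letters averaged and no channel effect the shares were 5.26% for TBP, 10.3% for TAF1, 1.22% for Spt3, 7.20% for Mot1 and 9.11% for Bdf1. Beyond Null they were 0.4999% for TBP, 1.08% for TAF1, 0.0781% for Spt3, 1.81% for Mot1 and 1.19% for Bdf1, and 0% for Spt3 against TAF1. A fit of each group or pair of groups alone gave 0% for TAF1, 0% for Spt3, 0% for Null, 0% for input DNA, 3.17% for Mot1 and 5.50% for Bdf1. Beyond Null it gave 0.125% for TBP, 0% for TAF1, 0% for Spt3, 0.156% for Mot1 and 0% for Bdf1, and 0% for Spt3 against TAF1. The RNA heat arrays alone, without a channel effect, gave 19.8%. All of these analyses have fewer values to estimate the spread from, and those without a channel effect change that as well. Which of these moved the counts was not tested, and a lost call alone does not show a smaller effect.

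A block for the replicate letter gave 5.69% for Mot1, 10.6% for Bdf1 and 0.0157% for Null, with 0.596% for Spt3 beyond Null, 2.19% for Spt3 against TAF1 and 18.3% for RNA. Letters did not mark paired arrays, as 8 of 78 pairs of arrays with the same letter correlated above 0.1 (median r = -0.0409), against 69 of 258 other pairs.

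For Null, regions with at least 2 arrays gave 0.0148% and a separate channel effect for input DNA gave 0.0156%. Without both noisier Null arrays the shares beyond Null were 2.28% for TBP, 4.87% for TAF1, 0.125% for Spt3, 2.22% for Mot1 and 3.19% for Bdf1. The cause was not tested.

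With each array left out in turn the shares ranged from 6.36% to 9.65% for TBP, 9.76% to 18.2% for TAF1, 2.02% to 5.12% for Spt3, 7.01% to 14.9% for Mot1, 6.67% to 14.5% for Bdf1, 0% to 10.5% for Null and 0.0156% to 0.0156% for input DNA. Beyond Null they ranged from 3.67% to 9.31% for TBP, 5.44% to 13.0% for TAF1, 0.391% to 4.61% for Spt3, 4.31% to 10.3% for Mot1 and 3.83% to 11% for Bdf1. Spt3 against TAF1 ranged from 1.44% to 4.83% and RNA from 17.4% to 35.6%.

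With an estimated correlation 8 lists were called for TBP (13 before), 5 for TAF1 (10), 7 for Spt3 (11), 2 for Bdf1 (4) and 1 for Spt3 minus TAF1 (6). For Bdf1 fry called 7, regions of 1 promoter gave 2, and arrays left out gave 4 to 7. For Null, arrays left out gave 0 to 2 lists.

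The shift of Null at RNA-induced genes was -0.02, and -0.0433 at genes induced at least 2-fold, which passed (camera adjusted p = 0.0286, and adjusted p = 0.296 with an estimated correlation). With arrays left out it ranged from -0.0406 to -0.0137. That of Spt3 at RNA-repressed genes was 0.04 and ranged from 0.0139 to 0.0487. With an estimated correlation no shift of a single factor or of Null kept its call over all RNA-repressed genes, while the differences TBP minus Null (adjusted p = 0.0461), TAF1 minus Null (0.0402) and Spt3 minus TAF1 (0.0183) did. At genes repressed at least 2-fold TBP (0.0226) and TAF1 (0.0333) passed on their own. Over all RNA-repressed genes the shifts were -0.0897 for TBP (camera adjusted p = 0.0518 with an estimated correlation), -0.109 for TAF1 (0.0517) and -0.0795 for Mot1 (0.181). They were -0.0980 for Bdf1 (0.0822) and 0.0444 for Null (0.428). The shift of Null ranged from 0.0301 to 0.0440 with arrays left out. The odds ratio of Spt3 calls at promoters was 2.04 beyond Null, without passing, against 1.52, and ranged from 1.04 to 2.66 with arrays left out. That of TBP then ranged from 4.08 to 7.69 (3.77 with all arrays) and that of Mot1 from 2.36 to 5.62 (3.27). The cause was not tested.

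Over regions with a value on every array r was 0.725 for TBP and TAF1 (0.612), 0.396 for TBP and Spt3 (0.259), 0.537 for TBP and Bdf1 (0.386), 0.333 for TAF1 and Spt3 (0.242) and 0.656 for TAF1 and Bdf1 (0.491). Without a channel effect r of Spt3 and Mot1 was 0.308 (0.394). With arrays left out r ranged from 0.516 to 0.608 for TBP and TAF1, 0.167 to 0.252 for TAF1 and Spt3, 0.289 to 0.402 for Spt3 and Mot1, 0.242 to 0.408 for TBP and Mot1, 0.145 to 0.292 for TBP and Spt3, and 0.0519 to 0.139 for Spt3 and Bdf1. Mot1 and Bdf1 reversed from 0.107 to -0.0124 without Mot1 array D, with a range of -0.0124 to 0.221. The cause was not tested.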

Other observations

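The differences between pairs of factors, at lists and at ZWF1 and HOR7, and the direction of TAF1 calls were chosen as tests only after the results were seen.

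At the promoter of ZWF1, the first enzyme of the pentose phosphate pathway, Bdf1 went apart from TBP, Spt3 and Mot1. TBP rose there by 0.88, Spt3 by 0.99 and Mot1 by 1.39, while TAF1 was at 0.16 and Bdf1 at -0.58, and its RNA rose by 1.43. At HOR7 the values were 0.96, 0.92 and 1.08 for TBP, Spt3 and Mot1, and 0.10 and -0.80 for TAF1 and Bdf1. Bdf1 minus TBP was -1.47 ± 0.17 at ZWF1 (limma adjusted p = 5.15e-05) and -1.76 ± 0.25 at HOR7 (0.000317), whereas TAF1 was not called different from TBP (limma adjusted p = 0.122 and 0.379) or from Bdf1 (0.124 and 0.238). TAF1 was called lower than Mot1 at both (limma adjusted p = 0.00027 and 0.0213) and lower than Spt3 at ZWF1 (0.00638) but not at HOR7 (0.062). SSE2 behaved otherwise, with rises for TBP (1.05), TAF1 (1.24) and Bdf1 (0.69).

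Across all regions the direct differences gave 628 calls for Bdf1 against Mot1, 452 for Bdf1 against Spt3 and 422 for Mot1 against TAF1. They gave 1 for TAF1 against TBP (304 at an unadjusted p under 0.05) and 0 for Bdf1 against TAF1 (485). A missed threshold does not show that those pairs responded equally.

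Bdf1 may fail to join chaperone promoters where TBP is gained. The median of Bdf1 minus TBP there was -0.36, with an adjusted p of 0.00171 by camera with an estimated correlation, which is consistent with a response of Bdf1 apart from that of TBP. That of Bdf1 minus TAF1 was -0.29 (0.00406 by the same test), and Bdf1 minus TBP also passed at general stress (-0.22, 0.00198) and cell wall stress promoters (-0.21, 0.0096). By that test Bdf1 minus TAF1 did not pass at general stress (-0.20, 0.062) or cell wall stress promoters (-0.20, 0.0541). At chaperone promoters Bdf1 minus Mot1 passed (-0.44, 0.00658) but Bdf1 minus Spt3 did not (-0.19, 0.134). ChIP of Bdf1 with a second epitope at HSP78 and HSP42 would test whether the tag plays a part.

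Mot1 may be recruited more to glycolytic than to proteasome promoters relative to TBP. The median of Mot1 minus TBP was 0.22 at glycolytic promoters (adjusted p = 0.0793) and -0.26 at proteasome promoters (adjusted p = 0.0793), both by camera with an estimated correlation, so the data cannot tell. Rapid loss of Mot1 before heat shock, followed by ChIP of TBP at TDH3 and PRE4, would separate these cases.

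TAF1 calls between convergent genes were mostly lower, whereas those at promoters were mostly higher (odds ratio 10.5, Fisher's exact test p = 1.08e-37). This was not particular to TAF1. Convergent regions had 54 lower and 12 higher calls for TBP, 45 and 11 for Spt3, 44 and 28 for Mot1, and 118 and 40 for Bdf1. Promoter calls of these factors were mostly higher too, but direction by class was tested in this way for TAF1 only. Across all 1367 such regions the TAF1 effect had little relation to the RNA change of the flanking genes (rho = 0.001 for the left one and -0.052 for the right one), so there is no support for reduced passage of transcription through the ends of repressed genes. A shift of the array median by strong promoters may be a cause, and heat shock with a spike-in of another yeast's chromatin would set the zero level and so test it.

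Histone promoters gained Mot1 while histone RNA fell, with 5 of 6 regions higher and a median RNA change of -0.89. The Mot1 medians over these regions were 0.10, 0.53, 0.47 and 0.47 on arrays A to D, so array A showed little of the rise. Those of TBP were 0.10, -0.07, 0.23 and 0.08, around 0 within their spread, which leaves open whether TBP was removed. Whether Mot1 represses these genes was not tested. The 8 sign patterns of the Mot1 arrays are too few to exclude chance (815 calls against 215 for the highest other, rank 1). Those calls were counted over all regions and do not bear on these 6 alone. Depletion of Mot1 and measurement of HTA2 RNA after heat shock would test it.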
